A study of Bos taurus with 18 samples.

How the data were processed

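Leukocyte RNA from 18 female cattle was profiled by mRNA sequencing: 6 Red Angus, 6 Droughtmaster and 6 F1 hybrids of both breeds. All 18 animals carried the heat stress label, and no animal outside that condition was analysed here, so the comparisons are between breeds and not between stressed and unstressed animals. Per the labels' protocols, blood was drawn from the tail vein into EDTA, centrifuged, and the white cell layer was taken into RNAiso Plus before RNA extraction and Illumina NovaSeq sequencing. Each group holds 6 animals with separate names, and the labels give no batch, pairing, parentage or collection date.

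The deposited table holds raw counts per gene for each library, as whole numbers that sum to different totals. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.16.1 were used with the genome build ARS-UCD1.2. The strandedness of the counting was not given in the sources used here, so reads of a locus and of an overlapping antisense gene cannot be told apart. The table lists 30162 features, of which 27607 carry an Ensembl identifier and 2555 are loci without one, for which a second deposited table gives chromosome, strand, start and end. These loci are called unannotated loci here. All 18 count columns matched a sample by its title. No pair of libraries agreed within sampling noise (smallest chi-square per degree of freedom 53.51, over features with a sufficient mean count).

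The files do not pair the Ensembl identifiers with gene names, and none of the 27607 identifiers matched the RefSeq table used for names (assembly ARS-UCD2.0; 0 matches). The 25 gene lists fixed before the data were examined (heat shock proteins, interferon response, blood cell type markers and others) could therefore not be tested, and 0 of them had a matched member. The rule for named genes required symbols and was replaced, before any test was run, by this one. In each comparison the 2 Ensembl identifiers with the largest log2 fold change in each direction were named, among those with an adjusted p under 0.05 and a mean of at least 5 CPM. Unannotated loci were named by position, 8 in each direction for Droughtmaster against Red Angus and 5 for the other comparisons, with a mean of at least 1 CPM. Where no gene passed, the identifier with the smallest p in each direction is given as not passing. Whether a named feature has near-identical copies elsewhere in the genome could not be assessed without names, so each is uncertain in that respect.

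Counts were tested with edgeR 4.0.16 in R 4.3.3. Features with low counts were removed with filterByExpr by group, which left 14446 features, 13439 of them with an Ensembl identifier and 1007 unannotated. Libraries were scaled by TMM, and all 18 libraries entered a single fit with 3 group means. The quasi-likelihood F test with robust estimation was used, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use the TMM-scaled library sizes, so the values of a library that a single feature dominates can sum to more than its nominal total. Log2 CPM values use a prior count of 2. Standard errors of log2 fold changes were derived from the F statistic. Comparisons were Droughtmaster minus Red Angus, F1 minus Red Angus, F1 minus Droughtmaster, and F1 minus the mean of both parental groups on the log scale (the mid-parent value). Genes were sorted into inheritance classes by the calls of the 3 pairwise tests. A gene was Red Angus-like where the parents differed and the F1 differed from Droughtmaster and not from Red Angus, and additive where the F1 lay between the parents and differed from both.

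The position of the F1 was summarised as the slope of F1 minus mid-parent on 0.5 times the parental difference, across the genes that differed between the parents. A slope of 0 places the F1 midway, -1 at the Red Angus level and 1 at the Droughtmaster level. Its 95% interval came from 1000 resamplings of animals within breeds. Measures of single libraries were compared between groups by exact two-sided permutation tests.

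The tests were tried on simulated counts with the means, library sizes and dispersions of these libraries and 200 genes changed in the 6 Droughtmaster libraries. For Droughtmaster against Red Angus, 0.5% of genes changed 2-fold were called, 66.5% at 4-fold with 5 false calls, and 90.5% at 8-fold with 8 false calls, over about as many genes as in the real data. With no gene changed, 0 calls were made. Genes were simulated independently of each other, without variation that many genes of an animal share. In the real libraries, a random split of F1 and Red Angus animals gave 1795 calls where the real split gave 0. The simulated numbers of false calls may therefore be too low for these libraries. When the F1 was simulated midway between parents that differed 4-fold, 0 genes were classed as additive and the slope was 0.025. When it was simulated at the Red Angus level the slope was -0.908. The class counts therefore cannot show additive genes of that size at this sample number.

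The tests and designs were kept as written before the data were examined. Alternatives set in advance were size factors of the DESeq2 type (RLE), the Wald test of DESeq2 1.42.0, no filter, a filter at a mean of 1 CPM, a fit of only the groups compared, each animal left out, an adjusted p under 0.01, a log2 fold change of at least 1, and classes by differences over 1.5-fold without tests. Alternatives added after seeing the data were 1 surrogate variable from sva 3.50.0, the most abundant feature of a Droughtmaster library left out, subsets of the Droughtmaster animals, 2 libraries left out together, adjustment over a subset of genes, and a cross-fitted slope. In the cross-fitted slope, genes were chosen and scaled in one part of the parental animals and the F1 was placed against the others, over 100 random partitions. The covariate for cell types, the removal of red cell genes and all tests of gene lists were not run, because identifiers could not be matched to symbols.

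Comparisons that share the Droughtmaster libraries were set against 5 data sets simulated without any change, again with independent genes. They were also set against the 20 divisions of those libraries into parts of 3. Chance was assessed by 100 splits of the libraries per comparison, the real one included.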

Results

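The data were leukocyte transcriptomes of Red Angus cattle (a Bos taurus beef breed), Droughtmaster cattle (a tropically adapted composite of Bos indicus and Bos taurus ancestry) and their F1 hybrids, with 6 females in each group, all labelled as under heat stress. The series asks how gene expression in leukocytes under heat stress is inherited by the hybrids. Libraries held between 11639027 and 24117615 counts. In units of 1e6 counts, the mean was 20.09 ± 2.61 (SD, n = 6) in Red Angus, 18.01 ± 3.1 in the F1 and 16.21 ± 2.54 in Droughtmaster. Of 30162 features, 7169 had 0 counts in every library.

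Leukocyte expression varied widely between animals of the same group. The median gene had an SD of 0.74 log2 CPM within Red Angus, 0.551 within the F1 and 0.589 within Droughtmaster (n = 6 each). The first principal component took 32.65% of the variance. It averaged -30.0 ± 70.0 in Red Angus and 32.0 ± 44.0 in Droughtmaster (SD, n = 6 each; exact permutation p = 0.0952, adjusted p = 0.412 over 6 tests of library measures). Red Angus replicates 4 and 2 and F1 replicate 2 lay lowest on it (-111.1, -95.05 and -96.1). They also had the fewest features with counts (15855, 15790 and 15507). Droughtmaster replicate 6 and Red Angus replicate 5, at 84.14 and 69.64, had the most (19605 and 19096), but Droughtmaster replicate 3, at 74.32, had 17084. Droughtmaster replicate 3 stood apart in composition: ENSBTAG00000037644 took 44.58% of its counts, against at most 0.409% in each of the other 17 libraries. A further 37 genes of at least 100 CPM in that library lay 16-fold or more above every other library, and held 11.4% of its counts. No other library had more than 1 such gene.

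The first comparison asked which genes differ between the parental breeds. A total of 376 genes differed between Droughtmaster and Red Angus leukocytes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 217 of them higher and 159 lower in Droughtmaster. The median change was 2.06 on the log2 scale among the higher genes and -1.41 among the lower ones, and 336 of the 376 changed at least 2-fold. In the simulated comparison, 0.5% of 2-fold and 66.5% of 4-fold changes were called, so passing favours large estimates. Sizes among called genes, here and in the later comparisons, may therefore be too large. Of the 217 higher genes, 191 carried an Ensembl identifier and 26 were unannotated loci. Of the 159 lower genes, 157 carried an identifier and 2 were unannotated. Without any adjustment, 2856 of the 14446 genes had p under 0.05.

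Unannotated loci that differed between the breeds were mostly higher in Droughtmaster, 26 of 28. The 28 loci lay on 17 chromosomes and 2 unplaced scaffolds. The share higher in Droughtmaster was 92.9% of these loci (exact 95% binomial interval 76.5% to 99.1%) and 54.9% of the called genes with an Ensembl identifier (Fisher's exact test across genes, two-sided, p = 3.6e-05; genes are not independent replicates). Called Ensembl genes drawn to match these loci on mean abundance had a mean share of 67.9%. The share of all counts that fell on unannotated loci did not pass a test between groups. With the most abundant feature of Droughtmaster replicate 3 set aside, they held 1.12% ± 0.258 of counts in Droughtmaster, 0.967% ± 0.132 in the F1 and 0.927% ± 0.287 in Red Angus (SD, n = 6 each; exact permutation p = 0.275 for Droughtmaster against Red Angus, adjusted p = 0.412). The 26 loci became 79 without Red Angus replicate 5, 15, 14 and 14 without Red Angus replicates 1, 3 and 4, and 16 and 11 without Droughtmaster replicates 3 and 6. They became 3 when only the 12 parental libraries entered the fit, and 2 at an adjusted p under 0.01.

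Positions of these loci are on ARS-UCD1.2, as the deposited table gives them, and their place relative to annotated genes was not analysed here. A locus on chromosome 4 (69676799 to 69690991, plus strand) was higher in Droughtmaster by 2.51 ± 0.444 (log2, SE; adjusted p = 0.00787). It measured 9.77 ± 5.45 CPM in Droughtmaster, 1.71 ± 0.903 in Red Angus and 1.86 ± 0.730 in the F1 (SD, n = 6 each), and all 6 Droughtmaster libraries lay above every Red Angus library. A pair of loci on chromosome 13, 118.3 kb apart and on opposite strands, were both higher. The locus at 78208837 to 78224080 (plus strand) was higher by 2.79 ± 0.545 (adjusted p = 0.0123), at 15.2 ± 16.9 CPM in Droughtmaster and 2.18 ± 0.71 in Red Angus. The locus at 78087589 to 78090530 (minus strand) was higher by 3.12 ± 0.655 (adjusted p = 0.0174), at 2.62 ± 1.56 against 0.301 ± 0.275 CPM. Both were higher in 6 of 6 Droughtmaster libraries than in any Red Angus library. On chromosome 5, the locus at 99453513 to 99460573 was higher by 3.80 ± 0.796 (adjusted p = 0.0174). It measured 78.6 CPM in Droughtmaster replicate 6 and 1.64 to 12.8 in the other Droughtmaster libraries, 4 of 6 lay above every Red Angus library, and without replicate 6 its change was 2.38 (adjusted p = 0.0551). A second called locus lay 505.7 kb from it. A locus on chromosome 16 (71032377 to 71072488) was higher by 2.62 ± 0.567, and one on chromosome 24 (1976657 to 1987261) by 2.64 ± 0.687. In the other direction, a locus on chromosome 4 (5745992 to 5765405) was lower, with a log2 fold change of -1.74 ± 0.427 (adjusted p = 0.0378), at 1.32 ± 0.737 CPM in Droughtmaster and 4.39 ± 1.26 in Red Angus. With only the 12 parental libraries in the fit, the adjusted p was 0.0307 for the first chromosome 4 locus. It was 0.0542 and 0.0572 for the chromosome 13 pair, 0.0666 for the chromosome 5 locus, 0.0595 on chromosome 16, 0.0946 on chromosome 24 and 0.105 for the locus lower in Droughtmaster. Without Droughtmaster replicate 3 the loci on chromosomes 16 and 24 (adjusted p = 0.0538 and 0.0787) and the lower one (0.0633) did not pass either, nor did these 3 without Droughtmaster replicate 6 (0.0534, 0.0878 and 0.0783).

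A locus on an unplaced scaffold (43652 to 296935, plus strand) was nearly silent outside Droughtmaster. It held 574 counts over 5 of the 6 Droughtmaster libraries and 0 in replicate 2. In Red Angus it held 5 counts over 2 libraries, and in the F1 27 counts over 2 libraries, with 4 libraries at 0 counts in each of those groups. The fitted log2 fold change between the parents was 6.93 ± 1.32 (adjusted p = 0.0113), a value that rests on those 5 Red Angus counts. The locus on chromosome 19 (12782309 to 12788984) had a log2 fold change of 5.15 ± 1.21 (adjusted p = 0.0302). It measured 120 CPM in Droughtmaster replicate 3 and at most 5.27 CPM in the other Droughtmaster libraries, and without that library its change was 2.16 (adjusted p = 0.195).

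**Figure D1:**
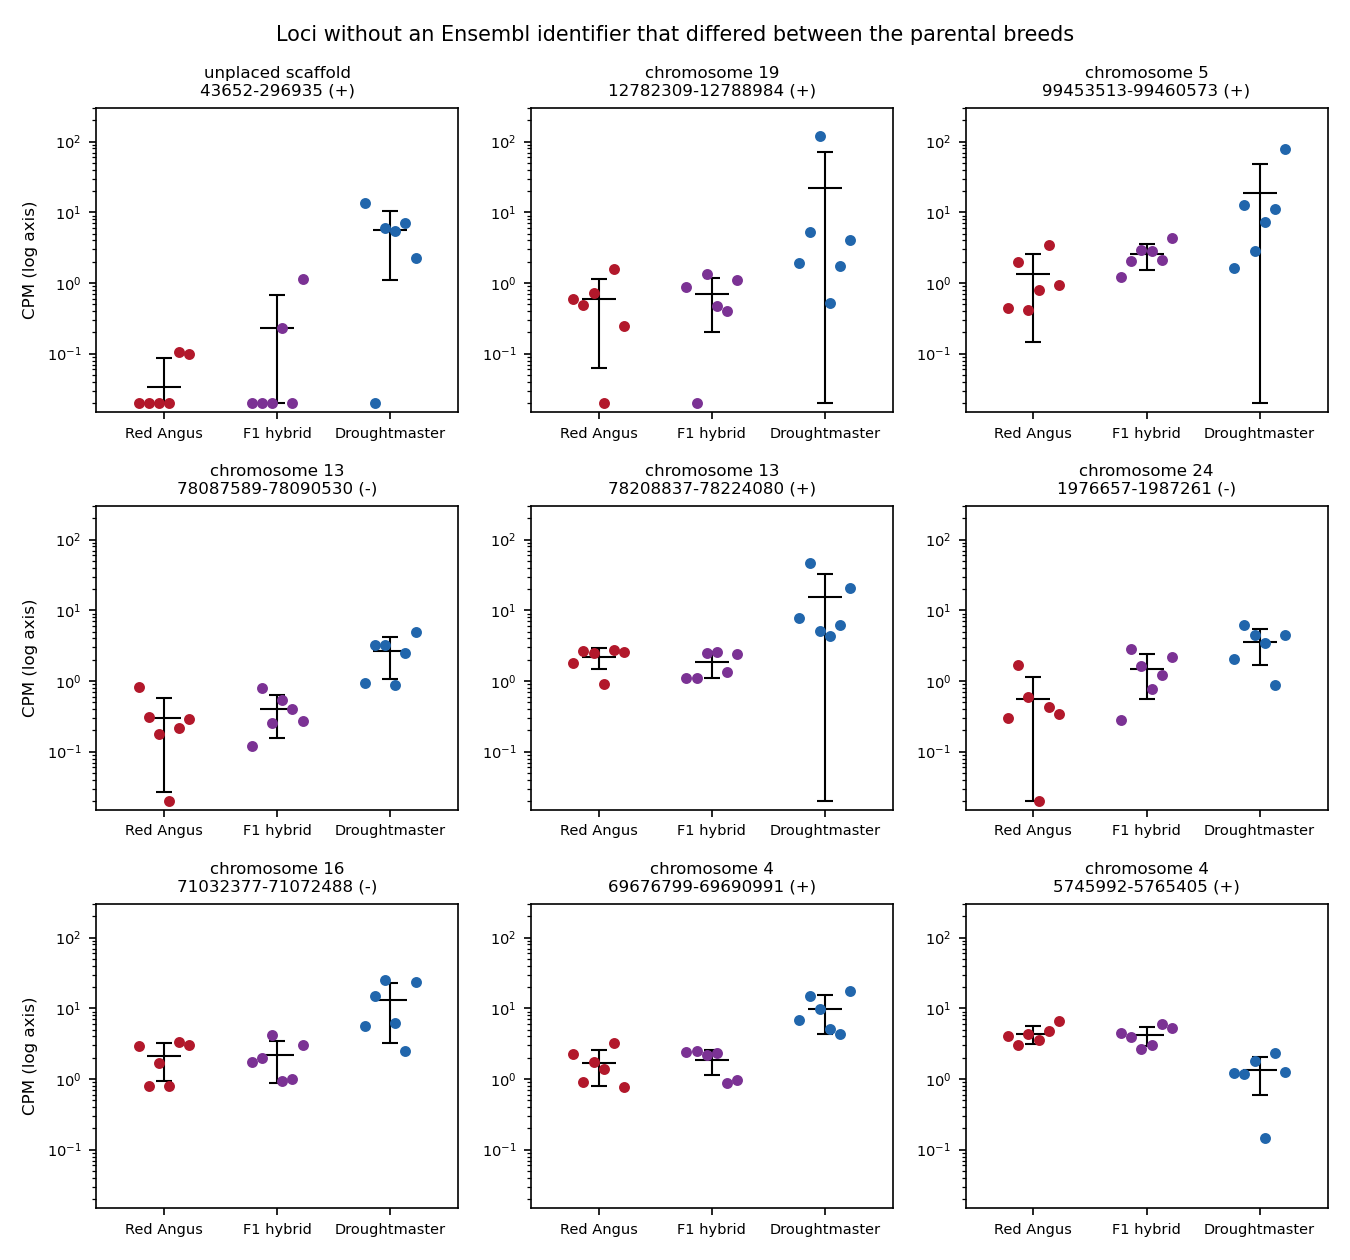
CPM of the 9 named unannotated loci in each library, on a log axis, with 6 animals per group; the horizontal mark is the group mean, the bar its SD, and values under the axis, including 0, are drawn at the bottom edge. All 6 Droughtmaster animals lie above every Red Angus animal at the chromosome 13 pair and at 69676799 on chromosome 4.

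Among features with an Ensembl identifier and a mean of at least 5 CPM, ENSBTAG00000001735 was the most reduced in Droughtmaster. It measured 0.869 ± 1.81 CPM there, against 21.4 ± 10.6 in Red Angus and 7.86 ± 2.39 in the F1 (SD, n = 6 each; log2 fold change -4.51 ± 0.827, adjusted p = 0.0103), and 6 of 6 Droughtmaster libraries lay below every Red Angus library. Droughtmaster replicate 6 measured 4.56 CPM and the other Droughtmaster libraries 0 to 0.336. Without replicate 6 the log2 fold change was -7.12 (adjusted p = 1.49e-06). ENSBTAG00000047986 was lower as well (-3.85 ± 0.981, adjusted p = 0.0435; 0.0909 without Droughtmaster replicate 3). With only the 12 parental libraries in the fit, the adjusted p was 0.051 for the first and 0.0836 for the second. ENSBTAG00000013178 (8.10 ± 2.05, adjusted p = 0.0426) and ENSBTAG00000037644 (7.16 ± 1.92, adjusted p = 0.0497) had the largest increases among identifiers with a mean of at least 5 CPM. Both increases came from Droughtmaster replicate 3: without it the log2 fold changes were 0.636 (adjusted p = 0.753) and 0.180 (adjusted p = 0.939).

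The number of genes depended on single animals. Without Red Angus replicate 5 it was 1407, and it fell to 160, 226, 166 and 158 without Red Angus replicates 1, 2, 3 and 4, to 241 and 249 without F1 replicates 3 and 4, and to 149 and 143 without Droughtmaster replicates 3 and 6. It was 56 when only the 12 parental libraries entered the fit, 236 with no filter on low counts, 31 at an adjusted p under 0.01, and 1100 by DESeq2's Wald test. For F1 against Droughtmaster, a fit of only those groups gave 161 genes, against 171 in the main fit. The main fit shares 1 estimate of spread per gene over all groups. Red Angus had the widest spread (median gene SD 0.74 log2 CPM, against 0.551 in the F1). Whether this explains the fall to 56 was not tested. Between the parents, Droughtmaster replicates 3 to 6 alone gave 353 genes, and replicates 1 and 2 alone gave 3. The sample names of replicates 3 to 6 hold longer numbers. How far the calls, here and for F1 against Droughtmaster, rest on something particular to those 4 animals stays open. The subsets also differ in size, at 4 and 2 animals. A core of 101 genes passed with all animals and without each animal in turn, of which 54 were higher and 47 lower in Droughtmaster. It included 9 unannotated loci, all 9 higher in Droughtmaster, among them both chromosome 13 loci, the first chromosome 4 locus and the scaffold locus.

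**Figure D2:**
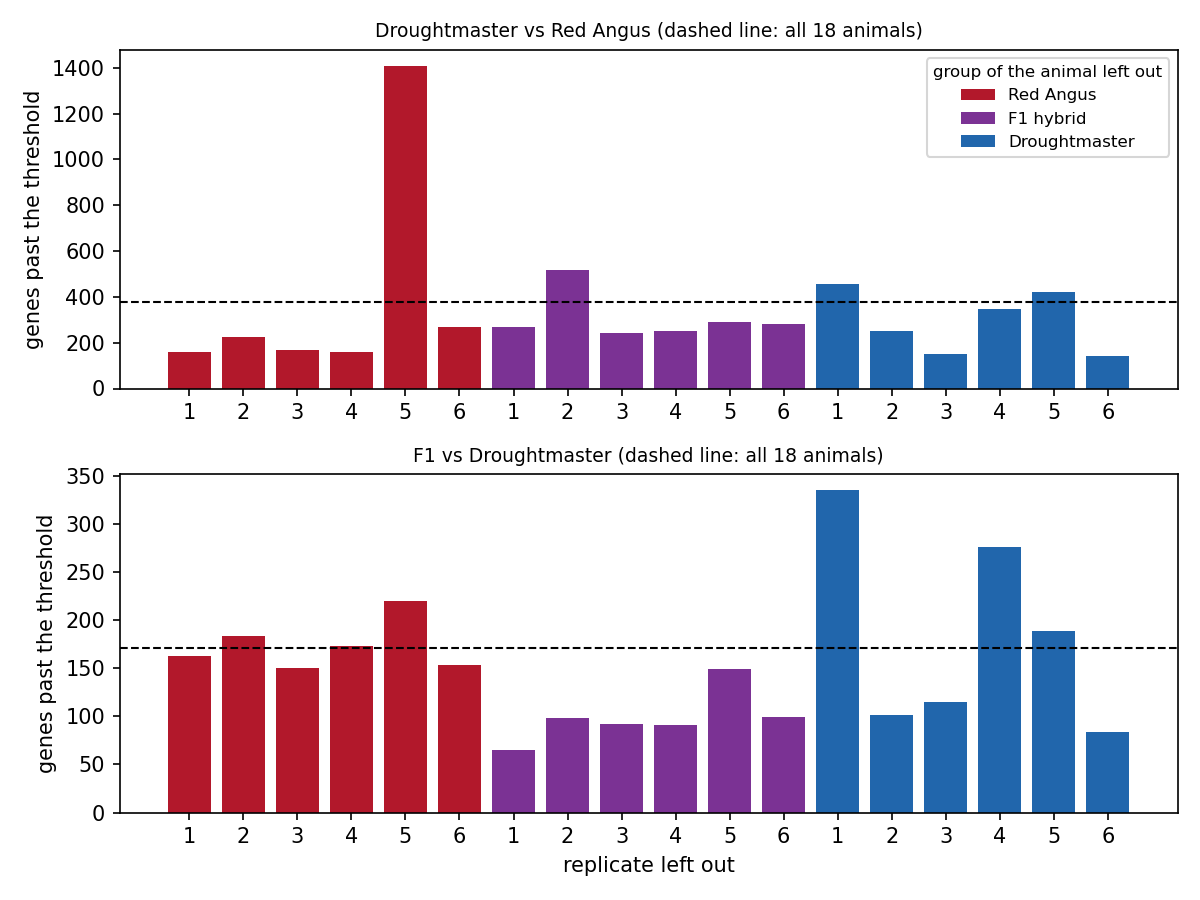
Number of genes past the adjusted threshold when each animal is left out, for Droughtmaster against Red Angus (upper panel) and F1 against Droughtmaster (lower panel); bars are coloured by the group of the animal left out and dashed lines mark the counts with all 18 animals, 376 and 171. The count for the parental comparison reaches 1407 without Red Angus replicate 5.

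The second comparison asked whether the hybrids differ from their Red Angus parent breed. No gene passed the test between F1 and Red Angus leukocytes: edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and DESeq2's Wald test each called 0 genes. At an unadjusted p under 0.05 there were 466 genes by edgeR, or 3.23% of those tested. The smallest p in each direction belonged to ENSBTAG00000006383, at 233 ± 256 CPM in the F1 and 24.8 ± 22.7 in Red Angus, and to ENSBTAG00000021807, at 35.8 ± 31.5 and 272 ± 162 CPM (SD, n = 6 each; log2 fold changes 3.23 ± 1.00 and -2.92 ± 0.759, adjusted p = 1 for both). The median standard error of a log2 fold change in this comparison was 0.385. In the simulated parental comparison, with as many animals per group and 200 changed genes, 2-fold changes were called in 0.5% of genes. The share was 66.5% at 4-fold and 90.5% at 8-fold. The 0 calls here therefore do not exclude 2-fold differences, or 4-fold differences in a few genes. Within the limits of that simulation, they go against 4-fold differences in as many as 200 genes.

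The third comparison set the hybrids against Droughtmaster. A total of 171 genes differed, 44 of them higher and 127 lower in the F1, with median log2 changes of 1.25 and -2.38. With 1 surrogate variable in the fit, 318 were higher (41.5%, against 25.7%) and 449 lower. All 16 unannotated loci among the 171 genes of the main fit were lower in the F1. The chromosome 13 locus at 78208837 to 78224080 was lower in the F1 by a log2 fold change of -3.05 ± 0.552 (adjusted p = 0.00973), at 1.83 ± 0.716 CPM in the F1 and 15.2 ± 16.9 in Droughtmaster, and 6 of 6 Droughtmaster libraries lay above every F1 library. A locus on chromosome 9 (88519507 to 88522277, minus strand) was lower by -3.10 ± 0.7 on the log2 scale (adjusted p = 0.0319), at 0.268 ± 0.157 against 2.35 ± 1.31 CPM. A locus on chromosome 29 (50599695 to 50605824, minus strand) was lower by -2.94 ± 0.622 (adjusted p = 0.022), at 2.31 ± 1.23 CPM in the F1, 17.9 ± 16.1 in Droughtmaster and 4.83 ± 1.21 in Red Angus. The scaffold locus (log2 fold change -4.58 ± 1.11) and the chromosome 19 locus (-4.94 ± 1.2) had an adjusted p of 0.0479 each. Without Droughtmaster replicate 3 the chromosome 19 locus was at -1.9 (adjusted p = 0.363), and the adjusted p was 0.0842 for the scaffold locus, 0.0672 for the chromosome 9 locus and 0.0515 for the chromosome 29 locus, while the chromosome 13 locus passed (0.017).

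ENSBTAG00000006035 and ENSBTAG00000019406 had the largest increases in the F1 over Droughtmaster among those with a mean of at least 5 CPM. The first measured 130 ± 47.1 CPM in the F1, 93.9 ± 80.8 in Red Angus and 9.52 ± 9.06 in Droughtmaster (log2 fold change 3.76 ± 0.675, adjusted p = 0.00973), and the second 14.7 ± 5.02, 14.2 ± 7.89 and 1.58 ± 1.40 CPM (3.18 ± 0.509, adjusted p = 0.00702; SD, n = 6 each). For both, 6 of 6 Droughtmaster libraries lay below every F1 library. The largest reductions among identifiers with that mean, of ENSBTAG00000013178 (-8.60 ± 2.09, adjusted p = 0.0481) and ENSBTAG00000016413 (-8.36 ± 1.82, adjusted p = 0.0269), rested on Droughtmaster replicate 3. ENSBTAG00000016413 measured 520 CPM in that library and at most 2.26 CPM in the other Droughtmaster libraries, and without that library the log2 fold changes were -1.07 (adjusted p = 0.714) for ENSBTAG00000013178 and -2.09 (adjusted p = 0.265) for ENSBTAG00000016413.

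The count of 171 fell to 65, 98, 92, 91 and 99 without F1 replicates 1, 2, 3, 4 and 6, and to 101 and 84 without Droughtmaster replicates 2 and 6. It rose to 335 and 276 without Droughtmaster replicates 1 and 4, and was 650 by DESeq2's Wald test and 32 at an adjusted p under 0.01. With only the F1 and Droughtmaster libraries in the fit it was 161. Droughtmaster replicates 3 to 6 alone gave 245 genes, and replicates 1 and 2 alone gave 53. A core of 55 genes passed with all animals and without each animal in turn, 13 higher and 42 lower in the F1, with 4 unannotated loci among the lower ones.

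The calls of the parental comparison and of F1 against Droughtmaster overlapped in 115 genes, all 115 in the same direction relative to Droughtmaster. Both comparisons use the same Droughtmaster libraries. Independent lists of these sizes would share 2.39 genes in the same direction relative to Droughtmaster. With the Droughtmaster libraries divided so that each comparison used a different 3, the shared calls had a median of 0.5 (range 0 to 4 over 20 divisions). With only 3 Droughtmaster libraries each, the comparisons themselves called a median of 3.5 genes against Red Angus and 94.5 against the F1, so the shared calls under division do not measure the effect of sharing libraries. Across genes, which are not independent replicates, the log2 differences of Droughtmaster from Red Angus and from the F1 correlated at 0.832, against 0.5 in 5 simulated sets without any change and a median of 0.420 with divided libraries. Their covariance was 0.519, against 0.109 in the simulated sets (a difference of 0.410) and a median of 0.289 (range 0.204 to 0.343) with divided libraries, where no library is shared.

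By the class rules, 115 of the 376 genes were Red Angus-like, 82 of them higher in Droughtmaster and 33 lower, and 10 of the 115 were unannotated loci. The class included both chromosome 13 loci and ENSBTAG00000019406. In 65 of the 115 genes the F1 mean lay beyond the Red Angus mean, which choosing genes by a difference between F1 and Droughtmaster favours. No gene was classed as additive, Droughtmaster-like, above both parents or below both parents, each at 0 by edgeR and at 0 by DESeq2, since those classes need a difference between F1 and Red Angus. Another 317 genes had a call that fitted none of these classes. A Red Angus-like class rests on a test that did not pass. Tested against the mid-parent value, 0 genes passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (smallest adjusted p = 0.384), and DESeq2's Wald test called 58. By edgeR, 863 genes had an unadjusted p under 0.05, or 5.97% of those tested, close to the share that this threshold gives without any difference. The smallest p in each direction were those of ENSBTAG00000016223, at 11.2 ± 3.05 CPM in the F1, 6.44 ± 3.18 in Red Angus and 3.66 ± 1.19 in Droughtmaster, and ENSBTAG00000008353, at 18.6 ± 8.15, 42.6 ± 31.4 and 96.3 ± 38.2 CPM (SD, n = 6 each). Of the 376 genes that differed between the parents, 123 (32.7%) had an unadjusted p under 0.05 against the mid-parent value. The class count ranged from 44 without Droughtmaster replicate 6 to 215 without Droughtmaster replicate 1, and was 70, 61, 57, 66, 67 and 70 without Droughtmaster replicates 2 and 3, F1 replicates 1, 3 and 4 and Red Angus replicate 3.

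Across the 376 genes that differed between the parents, the F1 lay nearer to Red Angus. The F1 mean was closer to the Red Angus mean for 340 genes (90.4%) and closer to the Droughtmaster mean for 36 (9.57%). It lay outside the parental range for 76 of the 376 genes. The slope of the F1 position was -0.630 (95% interval from resampling animals -0.896 to -0.347), where 0 is midway and -1 the Red Angus level. This interval holds the genes fixed, although the same animals chose them. Cross-fitted, with the genes chosen in other parental animals, the slope was -0.892 (jackknife SE 0.526) and its upper bound at 2 SE was 0.16, which does not exclude 0. In the main fit, the slope over all 14446 tested genes was -0.3996 (no interval computed), and it was -0.693 over the 217 genes higher in Droughtmaster and -0.506 over the 159 lower ones. Without Red Angus replicate 5, with the genes chosen again, the slope was -0.277.

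**Figure D3:**
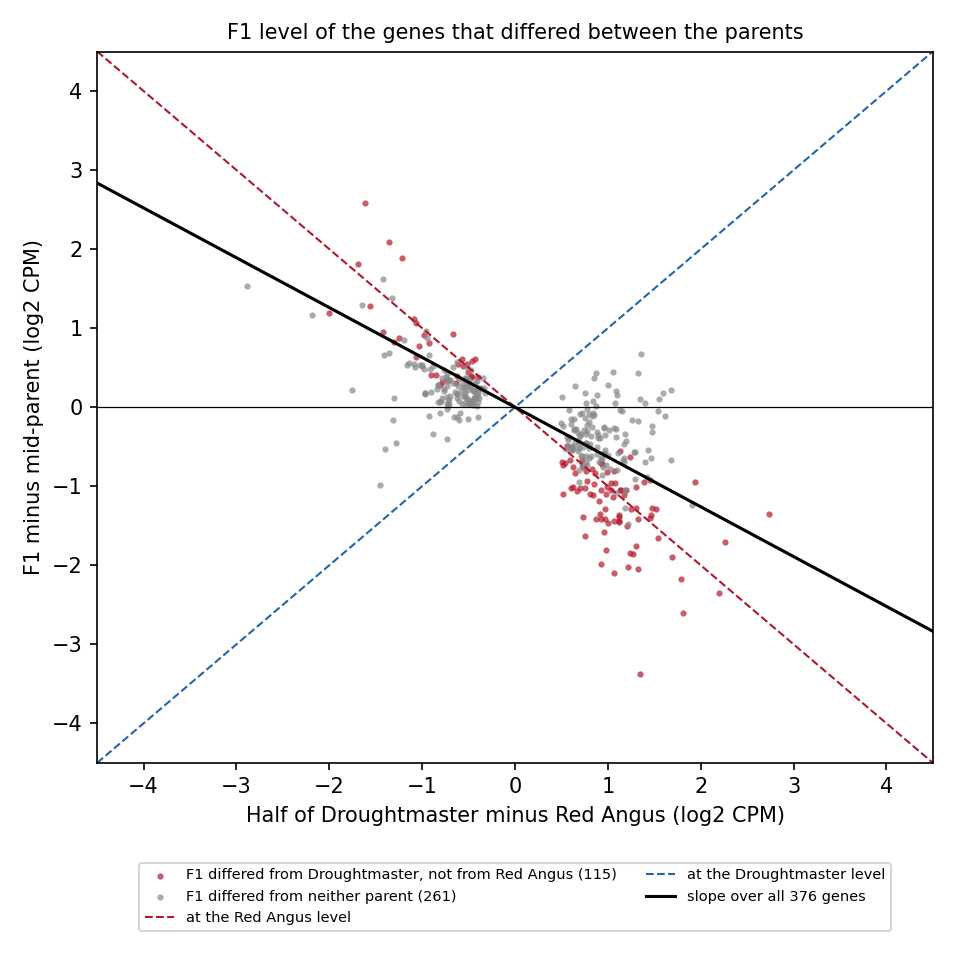
Each point is 1 of the 376 genes that differed between the parents, with 0.5 times the parental difference on the x axis and F1 minus mid-parent on the y axis, both in log2 CPM; dashed lines mark the levels of Red Angus and Droughtmaster. The black line is the slope of -0.630, which lies between the midway line and the Red Angus level.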

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

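The test that left the most abundant gene out before scaling was chosen after its result had been seen, as was the reading of it given here; the other tests in this part were set before their results were seen. Of 84 groups of 6 libraries examined, 11 held a library whose gap to its nearest neighbour was large for the range of the group. The rule would flag about 5% by chance, but that rate does not apply here. Most flagged groups were of features named for large changes in these same data. Droughtmaster replicate 3 accounted for 3 of the 11, in which ENSBTAG00000037644 counted both as CPM and as share of counts.

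In Droughtmaster replicate 3, ENSBTAG00000037644 stood at 1054361 CPM on the scaled library size, against 798 to 1686 in the other Droughtmaster libraries, and took 44.6% of the counts, against 0.0938% to 0.245%. ENSBTAG00000016413 measured 520 CPM there against 0.567 to 2.26. Leaving the abundant gene out before scaling kept 96.5% of the genes called between the parents, but it moved the effective size of this library by only -0.031 on the log2 scale. This gene itself therefore had little weight in the scaling of the library. The test does not decide whether the scaling of this library distorted the other genes in another way, which stays open. RNA of another cell type in this library remains open: 37 other genes of at least 100 CPM lay 16-fold or more above every other library, where 5 had been set as the number that this explanation needs. The same number may also come from a state of this animal's leukocytes, which was not tested, and no cell type was identified because the genes have no names here.

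The remaining libraries far from their group are given as values. The scaffold locus was at 0 CPM in Droughtmaster replicate 2, against 2.26 to 13.4 in the other Droughtmaster libraries. The chromosome 4 locus at 5745992 to 5765405 was at 0.144 CPM in Droughtmaster replicate 4, against 1.17 to 2.34. The chromosome 29 locus was at 0.145 CPM in F1 replicate 2, against 1.89 to 3.80 in the other F1 libraries. ENSBTAG00000021807 was at 4.02 CPM in Red Angus replicate 5, against 249 to 505 in the other Red Angus libraries. ENSBTAG00000016413 was at 0.398 CPM in F1 replicate 1, against 0.203 to 0.251, and ENSBTAG00000016223 at 17.4 CPM in the same library, against 9.12 to 10.7. Unannotated loci took 1.64% of counts in Droughtmaster replicate 6, against 0.984% to 1.09%. F1 replicate 2 had counts for 15507 features, against 17800 to 18811 in the other F1 libraries.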

How the results depend on the processing

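The surrogate variable, the left-out gene, the Droughtmaster subsets, the joint removal of 2 libraries, the adjustment over a subset and the cross-fitted slope were chosen after seeing the data. The covariate for cell types, the removal of red cell genes and the tests of gene lists were not run, since identifiers could not be matched to symbols. No paired analysis was possible because the labels give no number shared between animals of different groups. The causes of the shifts below were not tested, except that a stricter threshold lowers counts by construction.

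The genes called between Droughtmaster and Red Angus, 376, became 236 with no filter, 1100 with the DESeq2 Wald test, 56 with only the groups compared, 31 at an adjusted p under 0.01, 1079 with 1 surrogate variable, 3 with Droughtmaster replicates 1 and 2 only, and 651 without both Red Angus replicate 5 and Droughtmaster replicate 3. Leaving out each animal gave 143 to 1407. The 4 Droughtmaster animals other than replicates 1 and 2 alone gave 353, and 245 for F1 against Droughtmaster. Those 4 have longer numbers in their sample names. Subset size, 2 against 4 animals, was not varied apart from this. For F1 against Droughtmaster, 171 became 650 with DESeq2, 32 at the stricter threshold, 767 with 1 surrogate variable and 53 with Droughtmaster replicates 1 and 2 only, and 65 to 335 without each animal. For F1 against the mid-parent value, 0 by edgeR (863 genes, or 5.97%, at an unadjusted p under 0.05) became 58 with DESeq2, 3 with 1 surrogate variable, and 66 when adjusted over the 376 parental genes alone. F1 against Red Angus gave 0 genes by edgeR (466 at an unadjusted p under 0.05) and by DESeq2, and under every alternative run, as did the mid-parent test without each animal.

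Red Angus-like genes, 115, became 432 with DESeq2, 14 at the stricter threshold, 515 with 1 surrogate variable, 3 with Droughtmaster replicates 1 and 2 only, and 44 to 215 without each animal. Genes in no named class, 317, became 203 with no filter, 886 with DESeq2, 35 at the stricter threshold, 816 with 1 surrogate variable, 50 with Droughtmaster replicates 1 and 2 only, 599 without both libraries, and 139 to 1293 without each animal. Differences over 1.5-fold without tests gave 340 additive, 2269 Red Angus-like, 916 Droughtmaster-like, 199 above both parents, 392 below both parents and 2559 others. By tests, additive, Droughtmaster-like, above-both and below-both genes stayed at 0 without each animal. With only the 4 Droughtmaster animals other than replicates 1 and 2, 164 genes were Red Angus-like and 270 were in no named class.

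Unannotated loci higher in Droughtmaster, 26, became 81 with DESeq2, 3 with only the groups compared, 2 at the stricter threshold, 52 with 1 surrogate variable, 1 with Droughtmaster replicates 1 and 2 only, 17 with replicates 3 to 6 only, 50 without both libraries, and 11 to 79 without each animal. Those lower in Droughtmaster, 2, became 0 with no filter, 21 with DESeq2, 0 with only the groups compared, 0 at the stricter threshold, 10 with 1 surrogate variable, 0 with Droughtmaster replicates 1 and 2 only, 6 without both libraries, and 0 to 12 without each animal.

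The slope of the F1 position, -0.630, kept its sign under each alternative for which it was computed. It was not computed with DESeq2, with only the groups compared or with the 1.5-fold classes. It was -0.292 without both libraries, -0.892 when cross-fitted, and -0.728 to -0.277 without each animal. With size factors of the RLE type, 371 genes were called between the parents and 176 between F1 and Droughtmaster. Of 769 values of named features under alternatives, 559 kept their direction and side of the threshold, 206 lost the call and 3 gained it. The direction turned once, for ENSBTAG00000037644 between the parents, at -0.120 without both libraries (adjusted p = 0.933, largest over its alternatives 0.967). At these library sizes and this spread between animals, simulated 2-fold changes between Droughtmaster and Red Angus were called in 0.5% of genes and 8-fold changes in 90.5%. Depth, spread and the number of animals were not varied separately.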

Other observations

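The tests of neighbouring loci and the adjustment over the genes that differed between the parents alone were chosen after the data had been seen, as was the limit on the standard error of the cross-fitted slope. Log2 fold changes of neighbouring unannotated loci were correlated, and the cause was not tested. Among the 1007 tested loci, 195 neighbouring pairs lay within 100 kb of each other. Their log2 fold changes between Droughtmaster and Red Angus correlated across pairs (Pearson 0.331, Spearman 0.360; permutation p of the rank correlation = 1e-04, the smallest that 10000 permutations can give, and 0.00015 after Benjamini-Hochberg adjustment over 3 comparisons). The rank correlation was 0.512 for pairs on the same strand and 0.160 for the 86 pairs on opposite strands. These 2 values were 0.523 and 0.212 for F1 against Droughtmaster. For F1 against Red Angus the order was reversed, at 0.0966 for the same strand and 0.214 for opposite strands. For F1 against Droughtmaster the rank correlation over all pairs was 0.427 (Pearson 0.374, adjusted p = 0.00015), and for F1 against Red Angus 0.164 (Pearson 0.172, adjusted p = 0.021). Loci and pairs are not independent replicates.

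Adjusted over the 376 genes that differed between the parents alone, 66 genes differed between the F1 and the mid-parent value by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (smallest adjusted p = 0.0175). In all 66 the F1 lay on the Red Angus side. The animals that form the mid-parent value also chose these genes, so their chance values stay open here too.

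Random splits of the libraries, with groups of the real sizes, bear on the counts. For Droughtmaster against Red Angus, 2 of 100 splits gave at least the real 376 genes, the real one included, a share under 0.05 without adjustment over the 4 comparisons. Chance assignment of animals is excluded only in that sense, since the highest other split gave 2025 genes. That split, with several times the real count, points to a structure among the libraries, and it differed from the real one by exchanging Red Angus replicate 5 and Droughtmaster replicate 2. It had the widest gap on the first principal component of all 100 splits (94.8, against 62.1 for the real split), but the split with the next widest gap (75.1) gave 0 genes. For F1 against Droughtmaster, 1 of 100 splits reached 171 genes, the real one, and the highest other gave 28. For F1 against Red Angus and for the mid-parent test the real count was 0, so all 100 of 100 splits reached it, and the highest others gave 1795 and 7. The split with 1795 genes again had the widest gap on the first component of its 100, and splits with gaps of 83.3 and 71.9 gave 1503 and 965 genes, while one with a gap of 78.8 gave 0. The splits with 28 and 7 genes ranked 6 and 21 by that gap, so the component alone does not set the count.

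The position of the F1 nearer to Red Angus was weighed against 3 technical explanations. With genes called against Droughtmaster replicates 3 to 6, whose sample names hold longer numbers, the 2 other Droughtmaster animals lay above the F1 in the direction of the breed difference (slope 0.478, 95% interval 0.238 to 0.709), which argues against a reason particular to those 4 animals as the whole cause. Resampling had only these 2 held-out animals to draw from, so the interval may be too narrow. The slope was 0.335 with Droughtmaster replicate 1 only and 0.62 with replicate 2 only, against 0.847 for the 4 animals themselves, in which the genes had been called. A part particular to those 4 animals therefore stays open. With 1 surrogate variable in the fit the slope of the F1 position over the 376 genes was -0.689 (jackknife SE 0.148). It lay below 0 by more than 2 SE, which had been set in advance as the mark against the leading axis of variation. The surrogate variable was estimated with breed kept in the model, however, so it may miss an axis that runs along with breed. The leading axis therefore stays open. What it reflects, such as the mix of cell types or the number of features with counts, was not tested. Chance values of the parental libraries stay open: the cross-fitted slope was -0.892 (jackknife SE 0.526). It lay within 2 SE of 0, which is what had been set in advance as the mark of chance. The SE is also too wide to tell 0 from -1, the Red Angus level, so the test was read as undecided, a reading adopted after the value was seen. Inheritance of Red Angus-like levels by the hybrids may be the biological explanation, and it was not tested apart from these.

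The excess of unannotated loci higher in Droughtmaster was weighed in the same way. Only 0.16% of 10000 draws of called Ensembl genes matched on abundance held as large a share (mean share 67.9%, against 92.9% of the loci), although over all tested features the share with a positive change was 63.5% for unannotated loci and 62.3% for Ensembl genes of like abundance. The share never fell below 85.3% without any single Droughtmaster library, and was 83.9% with 1 surrogate variable (exact 95% interval 72.3% to 92.0%, against 49.9% of Ensembl genes). For the 28 called loci, these values argue against low abundance and a single Droughtmaster library as the whole cause. They do not extend to all tested features, where Ensembl genes of like abundance came close to the loci. The loci were also called about as often as Ensembl genes (2.78% against 2.59%). The surrogate variable was estimated with breed kept in the model, and the 49.9% was not matched on abundance, so the leading axis stays open. Droughtmaster replicate 6 and Red Angus replicate 5, high on the first principal component, held 1.64% and 1.43% of counts on unannotated loci. Red Angus replicates 4 and 2, low on it, held 0.655% and 0.792%. Droughtmaster replicate 3, also high on it, held 0.984%. Breed differences in expression may contribute, and so may differences in how reads of each breed align to the reference, which could not be tested from counts.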
